A study of Arabidopsis thaliana with 33 samples.

How the data were processed

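The series holds 33 samples of 10 day old Arabidopsis thaliana seedlings, accession Columbia-0: 28 DNA libraries from chromatin assays and 5 RNA samples, which were not analysed here. Groups were taken from the sample titles. The titles mark the chromatin libraries with D or F, and D was taken as DNase-seq and F as FAIRE-seq, the initials of the methods named in the design text. Each group had 3 libraries, except the cold groups with 2. Per the labels' protocols, nuclei were digested with DNase I for DNase-seq, tissue was fixed with formaldehyde for FAIRE-seq, and single-end reads were sequenced on a HiSeq 2000.

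The values used were 10 deposited peak lists, 1 per condition and assay, each linked by the labels to all libraries of its group. The lists therefore pool replicates, and how they were pooled is not given in the sources used here. Bowtie2, SAMtools, MACS2, FastQC, TopHat2 and the build TAIR10 are named, per the submitters' processing notes, without versions or settings, and trimming, duplicate removal and the background library are not given in the sources used here. A 5' cut site shift or fragment extension, which moves DNase-seq summits, is not given either. Each deposited list gives for every peak a fold enrichment over the local background (a ratio), as the authors' peak caller wrote it. The deposited lists also give −log10 of the p-value and of the q-value per peak, as the authors' peak caller wrote them, and all peaks had a −log10 q above 2. The deposited score column is 10 times −log10 q without its decimals, and was not used. The deposited summit column, of another kind, gives the summit's distance in bases from the peak start. These values were used only to rank, filter or describe peaks within 1 list. The lists hold no read totals, so the depth per library is unknown, and lists may differ in length through depth, enrichment or the number of libraries pooled.

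A peak of a stress list that shared no base with the control list of its assay was called gained, and a control peak that shared none with the stress list was called lost. Shares have 95% Wilson intervals, which cover counting error only. Shuffled positions are the mean of 20 shuffles within chromosomes. No test across peaks or genes was made, because each group has 1 list. The exact permutation test of the match between assays was one-sided, over all 24 pairings of the 4 DNase-seq with the 4 FAIRE-seq stresses, on the mean log2 of observed over expected genes, where the expected number is that of independent lists among 27444 protein-coding genes.

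Gene positions came from a RefSeq table of assembly TAIR10.1, which gives no strand, and no genome sequence was used here. The promoter window planned from transcription starts was therefore replaced by a window from 1000 bp outside to 200 bp inside either end of a gene. Location classes were reduced to within a gene, within 1000 bp outside a gene, and elsewhere, and a planned comparison of sequence motifs was not run. Random lists were matched on the distance to the neighbouring genes on both sides, in 10 classes, in place of the upstream neighbour alone. The placement of peaks against genes was checked in 25 blocks of 5 Mb, where the dip of summits lay 0 bp from gene ends in 10 blocks, 50 bp in 13, 100 bp in 1 and 150 bp in 1.

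The gene lists were fixed before the data were examined: heat shock response, cold response, drought and abscisic acid response, salt and ion homeostasis, touch, wound and jasmonate response, circadian clock, photosynthesis, endoplasmic reticulum stress, housekeeping, seed maturation, root cell types, and shoot meristem and leaf epidermis. All 244 genes on the 12 lists matched the gene table. Some genes are on more than 1 list. The number of members with a gained or lost peak is given with its percentile among 10000 random lists of the same size, as a description of these lists. The genes named per stress were the 10 with a gained peak in both assays that ranked highest by the lower of their 2 ranks within a list, the 10 with a lost peak in both assays ranked in the control lists, up to 10 members of the list of that stress gained or lost in both assays, and 4 genes fixed in advance. Of the ranked genes, some are given in the text. A peak between 2 genes counts for both.

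Alternatives planned in advance were a −log10 q of at least 5 in all lists or on 1 side, lists of equal length (45737 peaks in DNase-seq, 63060 in FAIRE-seq), at least 50% of a peak covered, summits within 150 bp, and gene-end windows of 500 bp outside to 100 bp inside and of 2000 bp outside to 500 bp inside. Those chosen after seeing the data were a window of the whole gene and 1000 bp either side, matching of random lists on control summits, the match of peaks in place of genes, all settings for the flank shares and for the percentiles of the stress lists, and equal numbers of strongest summits (4573 in DNase-seq, 6306 in FAIRE-seq). The steps were tested on simulated data. In a control DNase-seq list with 200 peaks removed and 200 added, 200 lost and 200 gained peaks were recovered. Against the DNase-seq peaks gained under cold, 5.5% of 200 random lists of 31 genes lay over percentile 95, and 97% did once 8 members were made gained. The tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.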

Results

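Open chromatin was profiled in 10 day old seedlings of Arabidopsis thaliana, accession Columbia-0, after 4 abiotic stresses and in an unstressed control. The stresses were heat at 38 °C for 6 h, cold at 4 °C for 24 h, 250 mM sodium chloride for 6 h and air drying for 1 h, called drought below. DNase-seq sequences the DNA that the nuclease DNase I frees from accessible chromatin, and FAIRE-seq sequences the DNA left free of protein after formaldehyde fixation. Each assay had 3 libraries per condition, except cold with 2, and each group's libraries were represented by 1 pooled peak list. With 1 list per group there is no replicate error. A difference between lists therefore compares those lists, and its counting interval does not cover the spread between seedlings or libraries. Read depth per library is unknown here, because the lists hold peaks and no read totals. The DNase-seq lists held 70807 peaks in control, 57736 under heat, 64324 under cold, 55784 under salt and 45737 under drought. The FAIRE-seq lists held 72789, 85366, 63060, 90465 and 92034 peaks in the same order. The listed peaks covered between 12.7 Mb (drought, DNase-seq) and 26.4 Mb (drought, FAIRE-seq) of chromosomes 1 to 5.

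The strongest summits of the 2 assays lay in different parts of genes in control seedlings, and the full lists differed less. Of all control DNase-seq summits, 75.0% (95% Wilson interval 74.7 to 75.4) lay within protein-coding genes and 6.59% in the 1000 bp outside a gene end, and of all control FAIRE-seq summits 67.8% (67.4 to 68.1) and 14.5% did. Random positions fell within genes in 54.2% and in the flanks in 20.5% of cases. Of the strongest 10% of control DNase-seq summits, 94.0% (93.4 to 94.5) lay within genes and 2.80% (2.44 to 3.21) in the flanks. Of the strongest 10% of control FAIRE-seq summits, 44.8% (43.7 to 46.0) lay within genes and 35.7% (34.6 to 36.8) in the flanks. The density of strong control DNase-seq summits was highest 300 bp inside gene ends, at 3.07 times the mean, and lowest at the end itself, at 0.0656 times the mean. That of strong control FAIRE-seq summits was highest 100 bp outside gene ends, at 2.91 times the mean. Over all control summits the density was highest inside genes in both assays, 300 bp from the end at 1.97 times the mean in DNase-seq and 400 bp from it at 1.37 times in FAIRE-seq. Of the strongest 10% of the FAIRE-seq summits, 67.1% lay within genes in the salt list and in the drought list, and the flank share was 18.5% (17.7 to 19.3) for salt, 17.9% (17.1 to 18.7) for drought, 29.8% (28.9 to 30.8) for heat and 33.2% (32.1 to 34.4) for cold. These summits were ranked within lists of different length. With the 6306 strongest FAIRE-seq summits of each list, a number set after the data were seen, the flank shares were 36.3% in control, 32.1% for heat, 33.2% for cold, 20.4% for salt and 19.4% for drought. Over all FAIRE-seq summits the flank share was 14.5% in control, 12.0% for heat and for cold, 9.30% for salt and 9.48% for drought. The gene table gives no strand, so starts and ends of transcription were pooled.

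**Figure D1:**
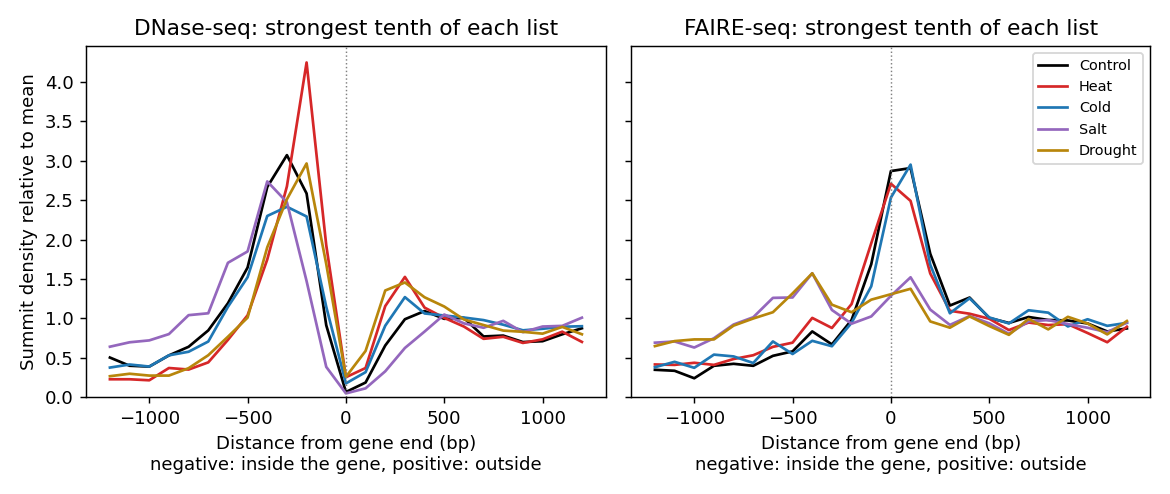
Density of peak summits by distance from the ends of protein-coding genes longer than 2400 bp, relative to the mean over 1200 bp either side, for the strongest 10% of each list; each line is 1 pooled list. DNase-seq lines dip at the gene end, to between 0.0480 (salt) and 0.258 (drought), while FAIRE-seq lines peak there in control, heat and cold (control 2.91) and are flatter under salt and drought.

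Peaks of the 2 assays coincided more than shuffled positions did in every condition. In control, 60.3% (60.0 to 60.7) of DNase-seq peaks shared at least 1 base with a FAIRE-seq peak, against 30.3% for shuffled positions. The share was 82.2% under heat, 65.3% under cold, 89.5% under salt and 86.4% under drought, against 37.0%, 24.1%, 41.4% and 39.6% for shuffled positions. The FAIRE-seq lists of salt, drought, heat and cold held 86.2%, 83.5%, 72.8% and 55.9% of the control DNase-seq peaks, where the control FAIRE-seq list held 60.3%. These lists covered 26.2, 26.4, 22.7 and 14.1 Mb, and the control list 17.5 Mb. A list that covers more bases holds more peaks by position alone, and no shuffled share was computed for these pairs. In the other direction, 63.5% of control FAIRE-seq peaks shared a base with a DNase-seq peak, and 58.0%, 69.9%, 56.8% and 42.1% did so under heat, cold, salt and drought.

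Each stress was then set against the control list of its assay. A stress peak that shared no base with a control peak is called gained, and a control peak that shared none with a stress peak is called lost. A gene is called gained or lost where such a peak has its summit between 1000 bp outside and 200 bp inside either gene end. A gene gained or lost in both assays need not have its peaks at the same site or at the same end. Fold enrichment and −log10 q of a peak are the authors' own values and describe a peak within its list only.

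Heat shock genes carried gained peaks under heat. Of the 37 genes of the heat shock response list, 20 had a gained DNase-seq peak, where 10000 random lists had 13.6 ± 2.95 (mean ± SD, percentile 98.3), and 17 had a gained FAIRE-seq peak, where random lists had 11.9 ± 2.82 (percentile 96.1). In both assays 10 members gained a peak, against 4.68 ± 2.02 (percentile 99.1). This was not particular to the list, since under heat 6 of the 25 salt and ion homeostasis genes (random 2.07, percentile 99.2) and 7 of the 39 drought and abscisic acid genes (random 3.32, percentile 97.1) also gained a peak in both assays. The 10 heat shock genes were HSFA2 (AT2G26150), a heat shock transcription factor, DREB2A (AT5G05410), a transcription factor of the drought and heat responses, APX2 (AT3G09640), an ascorbate peroxidase, MBF1C (AT3G24500), a heat-induced coactivator, CLPB3 (AT5G15450), a chloroplast chaperone, HSP90.1 (AT5G52640), the small heat shock protein genes AT1G07400, AT2G29500 and AT5G51440, and AT5G48570, which encodes a peptidyl-prolyl isomerase. DREB2A had no control summit at its ends in either assay. Its heat peaks lay on chromosome 5 (TAIR10) at 1604445 to 1604622 in DNase-seq, with a fold enrichment of 1.89, and at 1604335 to 1604740 in FAIRE-seq, with 2.52. The HSFA2 peaks lay on chromosome 2 at 11135096 to 11135377 (DNase-seq, fold enrichment 2.00) and 11135526 to 11135678 (FAIRE-seq, 2.44), and those of APX2 overlapped on chromosome 3 at 2955702 to 2955946 and 2955844 to 2956039. With 1 gained peak taken per gene and assay, the peaks overlapped at DREB2A and APX2 and at none of the other heat shock genes. Those of CLPB3 lay on chromosome 5 at 5018662 to 5018821 (DNase-seq) and 5013120 to 5013379 (FAIRE-seq). HSP101 (AT1G74310), a disaggregating chaperone, gained a FAIRE-seq peak on chromosome 1 at 27940189 to 27940306 and was open in both DNase-seq lists. HSP70 (AT3G12580) had summits in control and heat in both assays and no gained or lost peak. AT1G07400 also lost a DNase-seq peak and AT2G29500 a FAIRE-seq peak. In all, 5 members lost a DNase-seq peak (HSFA3, AT1G07400, HSA32, GolS1 and Hsp70b, named after their values were seen; AT1G07400 and Hsp70b also gained one), against 10.8 in random lists (percentile 1.42, and 2.74 when matched on control summits). Under drought, 4 members gained a DNase-seq peak, HSFB2A, AT-HSFB2B, which also lost one, BAG6 and Hsp70b, against 1.20 in random lists (percentile 98.0). Many of these peaks were weak in their lists: the MBF1C FAIRE-seq peak outranked 1.13% of the heat list and the HSP90.1 DNase-seq peak 4.28%. Each of the 10 genes shared at least 1 of these peaks with the end window of another gene, such as ftsh4 beside HSFA2. When random lists were also matched on control summits, the percentiles were 97.5 in DNase-seq and 94.9 in FAIRE-seq. In 5 of 7 settings tried the DNase-seq percentile lay between 94.0 and 95.9, and with a narrower gene-end window it was 99.995 (19 gained, random 8.38). The FAIRE-seq percentile was 54.3 with a wider gene-end window and 99.8 with a narrower one.

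Across the genome, heat brought 13886 gained DNase-seq peaks, 24.1% (23.7 to 24.4) of the heat list, and 27954 lost peaks, 39.5% (39.1 to 39.8) of the control list. In FAIRE-seq the gained peaks were 21167 (24.8%, 24.5 to 25.1) and the lost peaks 5859 (8.05%, 7.85 to 8.25). Gained DNase-seq peaks lay in gene flanks in 29.2% (28.4 to 30.0) of cases, against 6.59% (6.41 to 6.77) of all control DNase-seq peaks and 20.5% of random positions. By definition gained peaks share no base with control peaks, which lie mostly within genes, so the control share is no neutral baseline under any stress. The strongest genes gained in both assays were AT3G18500, AT5G43260, AT4G17720 with its neighbour SYP23 (AT4G17730, a syntaxin), MPI7 (AT1G04260), AT1G55335, AT5G66675, AT5G25500, and AT1G33770 with its neighbour AT1G33780. Of these, SYP23 and AT1G33780 also lost a DNase-seq peak, and MPI7, AT1G55335, AT5G66675 and AT1G33780 a FAIRE-seq peak. The peak between AT4G17720 and SYP23, on chromosome 4 at 9864790 to 9864991, had a fold enrichment of 3.59 and outranked 93.2% of the heat DNase-seq list. Among the strongest genes lost in both assays were CPUORF47 (AT5G03190), TPS10 (AT2G24210), a terpene synthase, and SGT1A (AT4G23570), a co-chaperone of immune receptors; CPUORF47 and SGT1A also gained a DNase-seq peak. Of 9551 genes with a gained DNase-seq peak, 71.0% had a control summit at an end, as did 72.7% of all protein-coding genes. Of the 9551 genes, 2048 also had a lost peak, and 26.9% of all protein-coding genes had one. In lists of equal length, gained and lost numbers can differ only where a peak overlaps more than 1 peak of the other list, so their balance shows little. Such lists for heat had 15235 gained and 15906 lost DNase-seq peaks and 11762 gained and 9636 lost FAIRE-seq peaks.

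Genes of cold acclimation carried gained DNase-seq peaks under cold. Of the 31 genes of the cold response list, 15 gained a DNase-seq peak, against 5.41 ± 2.12 in random lists and above all 10000 of them, and 2, COR314-TM2 and COR27, lost a peak, against 6.27 (percentile 2.19, and 9.51 when matched on control summits). In FAIRE-seq, 6 gained a peak (random 3.67 ± 1.77, percentile 89.2, and 98.0 with −log10 q of at least 5 on 1 side but 68.5 with lists of equal length) and 11 lost a peak (random 11.3). The 5 members gained in both assays (random 0.703 ± 0.827, percentile 99.9) were COR15B (AT2G42530), a chloroplast protein of freezing tolerance, COR413IM1 (AT1G29395) and its neighbour COR314-TM2 (AT1G29390), ADH1 (AT1G77120), alcohol dehydrogenase, and RHL41 (AT5G59820), a zinc finger factor also called ZAT12. COR413IM1 also lost a FAIRE-seq peak. The COR15B FAIRE-seq peak, on chromosome 2 at 17711142 to 17711451, had a fold enrichment of 5.06 and outranked 99.6% of the cold list. Some peaks of these genes were weak: in DNase-seq that of COR15B outranked 9.49% of the cold list and that of ADH1 2.56%. The COR413IM1 FAIRE-seq peak outranked 9.61%. With −log10 q of at least 5 in all lists, COR15B and ADH1 were not gained in DNase-seq, nor was COR413IM1 in FAIRE-seq. ADH1 had no control summit at its ends in either assay, and its cold peaks overlapped on chromosome 1 at 28977557 to 28977678 (DNase-seq) and 28977563 to 28977693 (FAIRE-seq). DREB1A (AT4G25480), the cold-induced transcription factor also called CBF3, had no control DNase-seq summit at its ends and a cold peak on chromosome 4 at 13017801 to 13017955 with a fold enrichment of 2.43. COR47 (AT1G20440), a dehydrin, gained a DNase-seq peak on chromosome 1 at 7086641 to 7086749 and lost a FAIRE-seq peak at 7084355 to 7084493. COR15A (AT2G42540) and KIN2 (AT5G15970) were open in both DNase-seq lists and lost a FAIRE-seq peak each. The cold list was not raised under cold alone: 18 of its genes gained a DNase-seq peak under heat (random 10.5, percentile 99.6) and 5 under drought (random 0.919, percentile 99.9), which were CBF2, COR47, COR27, HSFC1 and GRP7, named after their values were seen.

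Cold brought 7749 gained DNase-seq peaks (12.0%, 11.8 to 12.3) and 17673 lost peaks (25.0%, 24.6 to 25.3), and in FAIRE-seq 9897 gained (15.7%, 15.4 to 16.0) and 21101 lost peaks (29.0%, 28.7 to 29.3). Gained DNase-seq peaks lay in gene flanks in 22.2% (21.3 to 23.1) of cases, near the 20.5% of random positions. The strongest genes gained in both assays were AT4G32330, PAO3 (AT3G59050, a polyamine oxidase), AT2G15980 beside the cold list gene COR413-PM1, MT1A (AT1G07600, a metallothionein), AT1G21065, AT5G17560, CYP94B3 (AT3G48520, a hydroxylase of jasmonoyl-isoleucine), GTG1 (AT1G64990), AT3G59490 and AT3G59500. AT5G17560 and AT3G59500 also lost a DNase-seq peak, and AT5G17560 and GTG1 a FAIRE-seq peak. In MT1A the peaks of the 2 assays covered nearly the same bases of chromosome 1, 2338727 to 2338972 and 2338722 to 2338987, with fold enrichments of 2.72 and 3.18. The FAIRE-seq peak of AT2G15980, on chromosome 2 at 6950698 to 6951050, had a fold enrichment of 5.30. Among the strongest genes lost in both assays, SBP2 (AT4G14040, a selenium-binding protein), IDH-III (AT4G35650, an isocitrate dehydrogenase subunit) and GRP9 (AT2G05440, a glycine-rich protein) had no cold summit at their ends in either assay. The cold lists rest on 2 libraries each, where the control lists rest on 3. With summits matched within 150 bp, 15152 DNase-seq peaks were gained, and 13.1% of them lay in gene flanks.

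Of the 25 genes of the salt and ion homeostasis list, 0 gained a DNase-seq peak under salt, where random lists had 0.224 ± 0.475, too few for a count of 0 to stand low. When lists were of equal length 4 gained a peak, AVP1, KT1, MYB102 and MYBR1, named after their values were seen (random 0.946, percentile 99.2). These peaks share bases with weaker control peaks that the shortened control list leaves out, so they were not closed in control. With the lists at full length, 6 members gained a FAIRE-seq peak (random 6.64, percentile 39.6). Salt brought 8 members with a lost DNase-seq peak (random 5.97, percentile 83.0) and 6 with a lost FAIRE-seq peak (random 5.91, percentile 53.1). ZAT7 (AT3G46090), a zinc finger factor, lost a peak in both assays, on chromosome 3 at 16925089 to 16925241 (DNase-seq) and 16926907 to 16927059 (FAIRE-seq). SOS1 (AT2G01980), the plasma membrane sodium/proton exchanger, was open in both conditions in both assays. STZ (AT1G27730), also called ZAT10, gained a FAIRE-seq peak on chromosome 1 at 9650118 to 9650225. HAI1 (AT5G59220), a phosphatase of abscisic acid signalling, lost its DNase-seq peak on chromosome 5 at 23893533 to 23893643. LTI65 (AT5G52300), also called RD29B, lost a FAIRE-seq peak on chromosome 5 at 21240443 to 21240599 that outranked 91.9% of the control list. The salt list stood higher under heat, where 16 of its genes gained a DNase-seq peak (random 8.07, percentile 99.9).

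Salt brought few gained DNase-seq peaks, 1729 (3.10%, 2.96 to 3.25), and 15839 lost peaks (22.4%, 22.1 to 22.7). In FAIRE-seq it brought 31576 gained (34.9%, 34.6 to 35.2) and 9287 lost peaks (12.8%, 12.5 to 13.0). Of the gained DNase-seq peaks, 55.9% (53.6 to 58.3) lay neither in a protein-coding gene nor within 1000 bp of one, against 18.4% (18.1 to 18.7) of all control peaks and 25.3% of random positions. In gene flanks lay 4.80% (3.89 to 5.91) of them, against 6.59% of all control peaks and 20.5% of random positions. Lost FAIRE-seq peaks lay in gene flanks in 33.2% (32.3 to 34.2) of cases, and gained ones in 4.61% (4.39 to 4.85). The strongest genes gained in both assays included WRKY11 (AT4G31550), a transcription factor of the WRKY family, SmD3 (AT1G76300), a spliceosome protein, SELT (AT3G47300), SARA1A (AT1G09180) and SFR2 (AT3G06510), an enzyme of galactolipid remodelling. Their DNase-seq peaks were still weak, and in this order outranked 34.9%, 28.6%, 25.8%, 21.9% and 21.2% of the salt list. Their FAIRE-seq peaks outranked between 30.9% (SARA1A) and 70.4% (SELT) of theirs. SELT and SFR2 also lost a DNase-seq peak and SARA1A a FAIRE-seq peak. WRKY11 had no control DNase-seq summit at its ends, and its peaks of the 2 assays began 2 bp apart, at 15288767 and 15288765 on chromosome 4. Among the strongest genes lost in both assays were DAU1 (AT5G02390), EMB3147 (AT2G30200), BEN1 (AT2G45400) and TSC10B (AT5G19200), the last 2 with a gained FAIRE-seq peak as well. With lists of equal length, salt had 6062 gained and 5815 lost DNase-seq peaks and 15846 gained and 12417 lost FAIRE-seq peaks. With summits matched within 150 bp in place of a shared base, the flank share of lost FAIRE-seq peaks was 19.3%.

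Under drought, 13 of the 39 genes of the drought and abscisic acid response list lost a FAIRE-seq peak. Random lists lost 7.80 (percentile 97.6), but against random lists matched on control summits the percentile was 83.0, so the list did not stand apart from genes equally open in control. A gained FAIRE-seq peak was found at 9 members (random 11.1, percentile 23.3). In DNase-seq, 2 members, HAB1 and ABF3, gained a peak (random 1.02, percentile 82.3) and 10 lost 1 (random 10.7, percentile 40.3). When lists were of equal length, 9 members gained a DNase-seq peak (random 3.21, percentile 99.8), and with a wider gene-end window 6 did (random 1.57, percentile 99.8). In the lists of equal length, all of these peaks except those of HAB1 and ABF3 share bases with weaker control peaks that the shortened control list leaves out. The members lost in both assays were 4: LEA14 (AT1G01470), a late embryogenesis abundant protein, HB-7 (AT2G46680), a homeobox factor, RD22 (AT5G25610), and RAB18 (AT5G66400), a dehydrin (random 1.86, percentile 92.1). LEA14 also gained a FAIRE-seq peak. HB-7 lost its DNase-seq peak on chromosome 2 at 19164556 to 19165171, and RAB18 its peak on chromosome 5 at 26519469 to 26519585. The HB-7 peak outranked 57.0% of the control list, while the RAB18 peak was weak and outranked 4.35%. Neither gene had a drought DNase-seq summit at its ends. LTI78 (AT5G52310), also called RD29A, lost the same FAIRE-seq peak that its neighbour LTI65 lost under salt. NCED3 (AT3G14440), an enzyme of abscisic acid synthesis, lost a FAIRE-seq peak on chromosome 3 at 4834220 to 4834346, and RD26 (AT4G27410), a NAC factor, lost 1 on chromosome 4 at 13709125 to 13709291. ABF3 (AT4G34000), a factor that binds abscisic acid response elements, was the member gained in both assays, with peaks on chromosome 4 at 16295107 to 16295350 (DNase-seq, fold enrichment 5.25) and 16299191 to 16299345 (FAIRE-seq, 1.84), and it also lost a DNase-seq peak. Its gained peaks outranked 66.4% of the drought DNase-seq list, whose median fold enrichment was 4.42, and 27.4% of the drought FAIRE-seq list.

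Drought brought 971 gained DNase-seq peaks (2.12%, 1.99 to 2.26) and 28930 lost peaks (40.9%, 40.5 to 41.2). In FAIRE-seq it brought 31229 gained (33.9%, 33.6 to 34.2) and 7471 lost peaks (10.3%, 10.0 to 10.5). The few gained DNase-seq peaks lay in gene flanks in 33.9% (31.0 to 36.9) of cases, against 20.5% of random positions. Lost FAIRE-seq peaks did so in 36.0% (34.9 to 37.1), and gained ones in 4.74% (4.51 to 4.98). The strongest genes gained in both assays included RALFL21 (AT3G04735), a peptide signal, EXO70B2 (AT1G07000), an exocyst subunit, and APT2 (AT1G80050), an adenine phosphoribosyltransferase. All 3 also lost a peak, RALFL21 in DNase-seq, APT2 in FAIRE-seq and EXO70B2 in both. Among those lost were CYP97A3 (AT1G31800), a carotene hydroxylase, COAD (AT2G18250), an enzyme of coenzyme A synthesis, and EGY3 (AT1G17870), of which COAD and EGY3 also gained a FAIRE-seq peak. With lists of equal length, drought had 5319 gained and 8260 lost DNase-seq peaks and 15298 gained and 11855 lost FAIRE-seq peaks, and the flank share of gained DNase-seq peaks was 19.0%. With summits matched within 150 bp, that share was 8.71%, and the share of lost FAIRE-seq peaks was 19.4%.

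**Figure D2:**
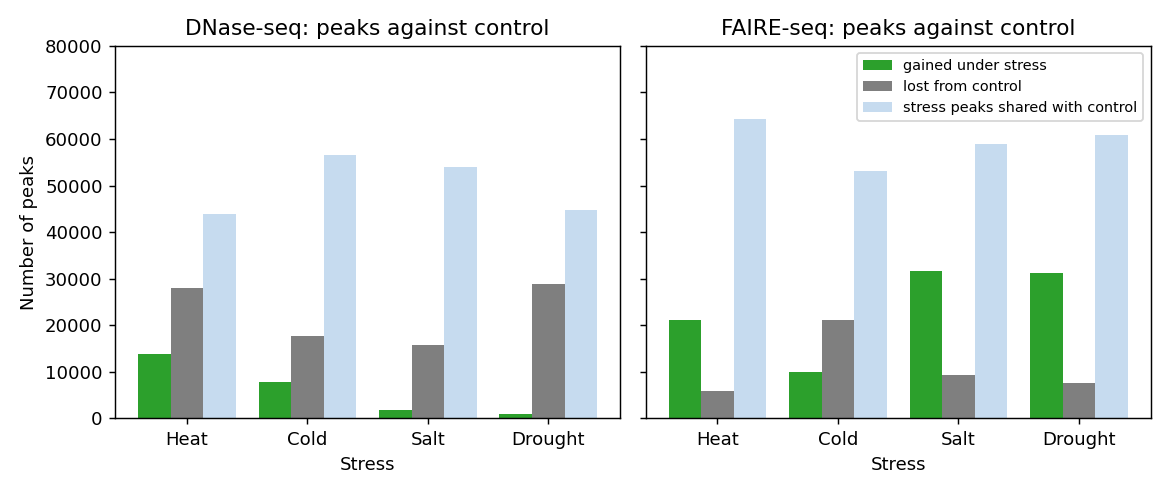
Numbers of peaks gained under each stress, lost from control, and shared with control, by assay; each bar is a count from 1 pooled list against the control list, with no replicate error. Drought shows 971 gained and 28930 lost DNase-seq peaks beside 31229 gained and 7471 lost FAIRE-seq peaks.

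**Figure D3:**
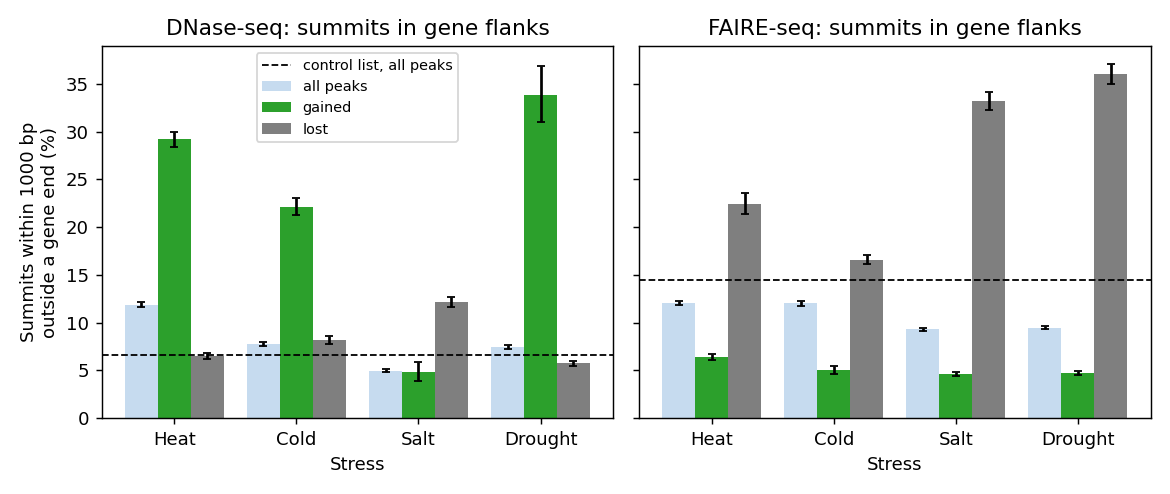
Share of summits in the 1000 bp outside the ends of protein-coding genes, in percent, for all peaks of each stress list, gained peaks and lost peaks, with 95% Wilson intervals; the dashed line is the control list. Gained DNase-seq peaks of heat (29.2%), cold (22.2%) and drought (33.9%) lie above the control list (6.59%) and those of salt (4.80%) below it, and lost FAIRE-seq peaks of salt (33.2%) and drought (36.0%) lie above theirs (14.5%). Random positions lay there in 20.5% of cases, and gained peaks exclude control peaks by definition.

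Gained and lost peaks were rare in the strongest 10% of each list. Their median −log10 q lay below that of shared peaks of the same list in every comparison. For FAIRE-seq peaks lost under salt and drought it lay little below, at 7.16 and 7.10 against 7.92. For DNase-seq peaks lost under salt it was 8.90 against 24.5. Of the strongest 10% of control DNase-seq peaks, heat lost 0.734%, cold 0.0424%, salt 0.0141% and drought 0 of 7080 peaks. Of the strongest 10% of stress peaks in FAIRE-seq, 0.0351% were gained under heat, 0.285% under cold, 0.0663% under salt and 0.0652% under drought. The highest such shares were 2.84% of the strong heat DNase-seq peaks gained and 3.79% of the strong control FAIRE-seq peaks lost under salt. In all comparisons the stress peaks shared with control, 65.1% to 97.9% of a list, exceeded the 27.0% to 34.3% of shuffled positions.

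Within an assay, the stresses changed overlapping regions to different extents. Of 18758 regions gained in DNase-seq, 72.8% were gained under 1 stress alone and 0.0853% under all 4, a share limited by the 971 peaks gained under drought. Of 45040 regions gained in FAIRE-seq, 38.1% belonged to 1 stress and 9.13% to all 4. For lost regions the order of the assays was the other way round: of 40836 in DNase-seq 31.5% were lost under 1 stress and 14.9% under all 4, and of 24615 in FAIRE-seq 58.2% and 10.7%. Cold alone accounted for 12013 of the 14316 FAIRE-seq regions lost under 1 stress, against 855 for heat, 1053 for salt and 395 for drought. The cold list is the shortest FAIRE-seq list and pools 2 libraries. Of the 24 pairs of stresses, counted per assay and for gained and lost genes, 23 shared more genes than independent lists would. The exception was heat and salt for gained DNase-seq peaks, with 93 shared genes against 93.3. In DNase-seq, 3808 genes gained peaks under both heat and cold, where independent lists would give 1707. In FAIRE-seq, 4702 genes lost peaks under both salt and drought, where independent lists would give 1254. The stresses share a control list, unchanged groups could not be simulated from lists without replicates, and the pooled control could not be split, so part of each excess may come from the shared control.

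The assays had separate control lists, so a match between them does not share a control. Genes gained in both assays under the same stress numbered 2978 under heat (2723 expected from independent lists), 670 under cold (614), 117 under salt (92.3) and 290 under drought (293). Genes lost in both numbered 918 (902), 2233 (2155), 1732 (1833) and 1538 (1741). Same-stress pairs did not match better than other pairs. The mean log2 of observed over expected gained genes was 0.15 for same-stress and 0.16 for other pairs (exact one-sided permutation test over 24 pairings, p = 0.625). For lost genes it was −0.05 and −0.07 (exact p = 0.333). The smallest p this design allows is 0.0417.

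**Figure D4:**
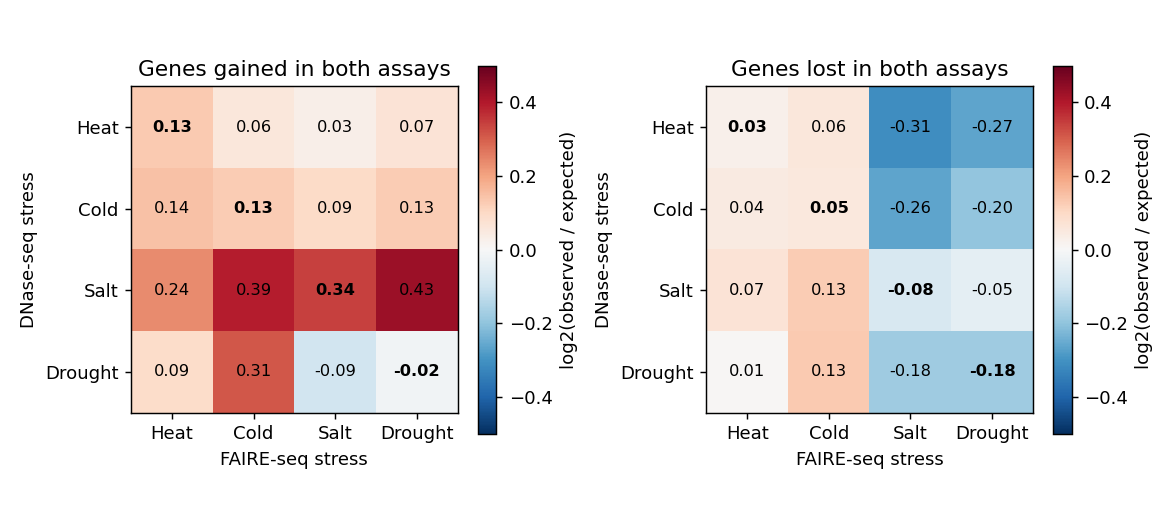
Log2 of observed over expected numbers of genes gained (left) or lost (right) in both assays, for each DNase-seq stress (rows) and FAIRE-seq stress (columns), with same-stress pairs in bold. Same-stress pairs average 0.15 for gained genes, against 0.16 for the other pairs.

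Among the lists chosen for other processes, the housekeeping list (15 genes) stood high under cold in DNase-seq, with 7 gained (random 2.72, percentile 99.5), and so did the endoplasmic reticulum stress list (14 genes), with 6 (random 2.54, percentile 98.3). The touch, wound and jasmonate list (19 genes) had 3 members gained in DNase-seq under drought (random 0.494, percentile 99.4): JAZ1, OPR3 and ERF5, named after their values were seen. The root cell type list (8 genes) had 5 gained in FAIRE-seq under drought (random 2.00, percentile 98.8): EXPA7, RHD6, SCR, PLT1 and MYB36, also named after their values were seen; MYB36 lost a FAIRE-seq peak as well. In the order heat, cold, salt and drought, gained DNase-seq peaks were found at 8, 6, 0 and 2 of the 17 circadian clock genes, 12, 7, 0 and 1 of the 25 photosynthesis genes, 1, 0, 0 and 0 of the 12 seed maturation genes, and 1, 0, 0 and 0 of the 7 shoot meristem and leaf epidermis genes. In FAIRE-seq the counts were 5, 4, 8 and 9 for the clock, 6, 2, 7 and 8 for photosynthesis, 4, 2, 6 and 5 for seed maturation, and 1, 0, 1 and 1 for shoot meristem and leaf epidermis. None of these last 4 lists passed percentile 97.5 for gained peaks in a single assay. In both assays together, 4 clock genes gained peaks under cold, ELF3, ELF4, FKF1 and AT5G64170 (random 0.474, percentile 99.9), the last 3 of which also lost a FAIRE-seq peak. Over all 12 lists, 4 stresses and 2 assays, 10 of 96 comparisons of gained genes passed percentile 97.5, where chance would give 2.4 if they were independent. For gained genes, 1 of 96 lay under percentile 2.5, the drought list under salt in FAIRE-seq, with 5 gained (random 10.5, percentile 1.84), namely ABI5, ERD14, LEA14, LEA7 and DREB2A, of which ABI5 and LEA14 also lost a FAIRE-seq peak. For lost genes, 1 of 96 passed percentile 97.5 and 3 lay under 2.5, and with matching on control summits 0 and 8 did. The lowest without matching was the cold list under drought in DNase-seq, with 3 lost, COR413-PM1, RHL41 and COR27, which also gained one (random 9.71, percentile 0.29, and 1.83 when matched). The genes of these last 2 comparisons were named after their values were seen.

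**Figure D5:**
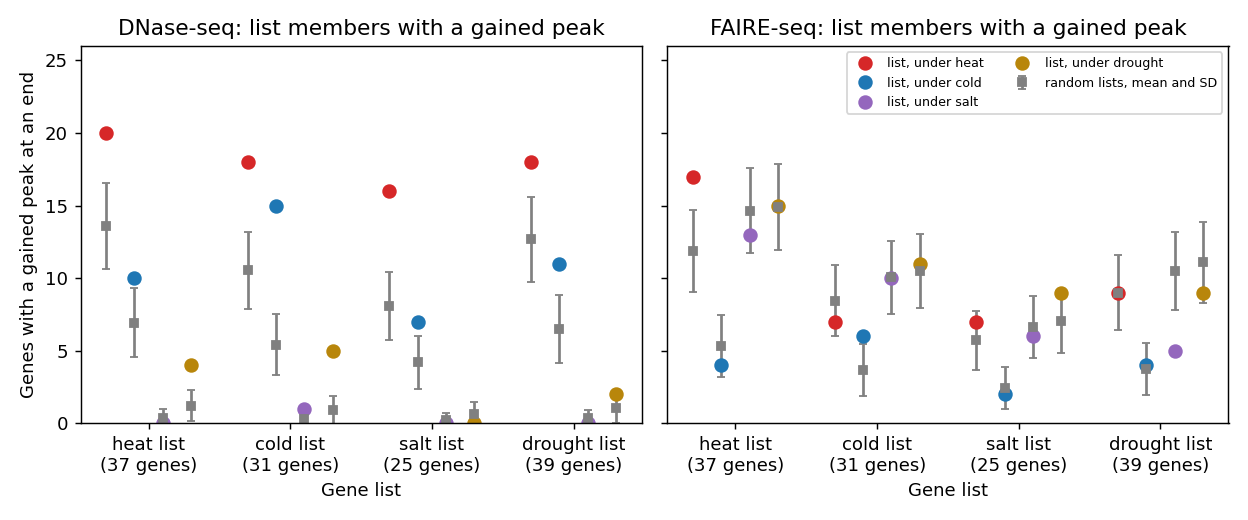
Number of genes with a gained peak at an end, for the 4 stress lists under each of the 4 stresses, as coloured points, beside the mean and SD of 10000 random lists matched on distance to neighbouring genes, as grey squares. The cold list under cold (15 genes) and the heat list under heat (20 genes) lie above random lists in DNase-seq, as do the cold list (18) and the salt list (16) under heat.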

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

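The tests of where DNase-seq summits lie, the settings for list percentiles, matching on control summits and the test of the cold list under other stresses were chosen only after the results were seen, and the tests of the strongest peaks and of neighbouring members were chosen after the list lengths, the strength of gained peaks and the gains of the gene lists had been seen but before the tests themselves were run.

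The DNase-seq and FAIRE-seq lists changed in opposite directions under heat, salt and drought. Compared with control, the DNase-seq list differed by −13071 peaks under heat, −15023 under salt and −25070 under drought, and the FAIRE-seq list by 12577, 17676 and 19245. The difference between the assays was not tested, since each group has 1 list. At most 0.734% of the strongest 10% of control DNase-seq peaks were lost and at most 0.0663% of the strongest 10% of stress FAIRE-seq peaks were gained in these 3 stresses, but such shares were at most 3.79% in every comparison, cold included, so the test decides nothing. Turnover of weak peaks, as from a difference in depth or enrichment between libraries, cannot be told apart from an effect of the stress on chromatin, because loss or gain of a strong peak was rare throughout and read totals were not used here.

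Strong DNase-seq summits lay inside genes and avoided gene ends, most clearly in control and under salt. Density around gene ends is the mean of the 100 bp bins centred at the end and 100 bp either side of it. A shift of coordinates between the lists and the gene table is argued against by strong control FAIRE-seq summits, which were 2.49 times as dense around gene ends as on average. Weak peaks as the source are argued against in control by the strongest 10% of DNase-seq summits, with a density of 0.388 around gene ends. Under stress the same density was 0.181 for salt, 0.546 for cold, 0.845 for drought and 0.851 for heat. These values lay on both sides of 0.5 and below the mean. Over all summits the density was 0.369, 0.532, 0.622 and 0.734, so weak peaks stay open for the density around gene ends in cold, drought and heat. At the end itself the strongest 10% had 0.0480 (salt), 0.175 (cold), 0.258 (drought) and 0.253 (heat). All summits had 0.215, 0.292, 0.366 and 0.443 there. At least 86.1% (cold) of the strongest 10% lay within genes, against 54.2% of random positions. For the dip at the end and the place within genes, these values argue against weak peaks in the stress lists. How reads were turned into pileups, the choice of fragment sizes, digestion depth and the background library were not tested and stay open, and no biological explanation was tested.

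Cold response genes gained DNase-seq peaks under cold, and heat shock genes gained peaks under heat, although the heat list's percentile in DNase-seq, 98.3, lay between 94.0 and 95.9 in 5 of the settings tried. With the narrow gene-end window it was 99.995. For the cold list, more frequent gains at genes already open in control are argued against by a percentile of 99.98 with matched random lists, and shared peaks of neighbouring members by a percentile of 99.99 with 1 member kept per group of neighbours (13 of 24 gained, random 4.15). The cold list also reached 99.9 under drought and 99.6 under heat, and under cold the housekeeping list (99.5) and the endoplasmic reticulum stress list (98.3) stood high as well, so the gains may reflect a property of these genes under several stresses, and may not be particular to cold response genes. For the heat list, matching on control summits moved the random mean only from 13.6 to 14.1 in DNase-seq (20 gained) and from 11.9 to 12.4 in FAIRE-seq (17 gained). The number of control summits thus accounted for little of the gap to random lists. The matched percentiles were 97.5 in DNase-seq and 94.9 in FAIRE-seq, near the edge of the random lists, so the test does not decide on the rest of the gap. An effect of each treatment stays open for both lists.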

How the results depend on the processing

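The settings for flank shares, list percentiles and strongest summits, and those of the whole gene, of matching on control summits and of peaks in place of genes, were chosen only after the results were seen. Over 11 settings, 78 results gave 352 values, of which 205 stayed within 1.5 times a count, within the counting interval of a share, or on the same side of the test or of percentile 97.5, 134 moved, 6 rose above percentile 97.5, 5 fell below it and 2 turned in direction. The lowest percentile of the cold list in DNase-seq over the 7 settings run for it was 99.6. The match of stresses across assays reached no p under 0.05 in any setting for gained or lost genes, nor with peaks in place of genes (mean log2 0.56, exact permutation p = 0.458, for gained and −0.66, p = 0.625, for lost peaks). For lost genes its mean log2, negative at first, was 0.00561 with lists of equal length (exact permutation p = 0.25) and 0.107 with the whole gene (p = 0.167). The cause was not tested for any of these changes, except that by construction the limit on 1 side cannot raise a count of peaks or genes, the narrow window cannot raise a count of genes, and the wide window and the whole gene cannot lower one. No paired analysis was possible because each list pools the replicates of its group, and leaving out each replicate was not run for the same reason. The motif alternatives were not run, because no genome was used. Matching by summits was run for peak counts and flank shares only, and coverage of at least 50% was not run for list members or their percentiles. Unknown depth limits every comparison of list lengths.

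With −log10 q of at least 5 in all lists, genes gained in both assays numbered 445 (cold). The percentiles of the list of a stress were 94.96 (heat) in DNase-seq. Flank shares of gained peaks were 25.5% (cold) and 30.8% (heat) in DNase-seq and 5.82% (cold) and 6.82% (heat) in FAIRE-seq. Flank shares of lost peaks were 7.56% (cold) in DNase-seq and 39.2% (drought), 24.0% (heat) and 36.7% (salt) in FAIRE-seq. With that limit on 1 side, gained peaks numbered 4960 (cold) and 980 (salt) in DNase-seq and 4371 (cold) and 13403 (heat) in FAIRE-seq. Lost peaks numbered 13707 (cold) and 3456 (heat) in FAIRE-seq. Genes gained in both assays numbered 242 (cold), 1954 (heat) and 63 (salt). Genes lost in both assays numbered 567 (heat). The percentiles of the list of a stress were 98.0 (cold) in FAIRE-seq and 95.9 (heat) in DNase-seq. Flank shares of gained peaks were 27.1% (cold), 37.5% (drought), 31.5% (heat) and 6.02% (salt) in DNase-seq and 6.63% (cold) and 7.69% (heat) in FAIRE-seq. Flank shares of lost peaks were 21.3% (cold), 41.5% (drought), 30.4% (heat) and 37.9% (salt) in FAIRE-seq and 12.8% (salt) in DNase-seq. With at least 50% of a peak covered, genes gained in both assays numbered 203 (salt). Flank shares of gained peaks were 4.62% (cold), 4.49% (drought), 6.01% (heat) and 4.35% (salt) in FAIRE-seq and 26.9% (heat) in DNase-seq. Flank shares of lost peaks were 7.64% (cold) and 5.38% (drought) in DNase-seq and 15.5% (cold), 33.6% (drought), 20.7% (heat) and 31.2% (salt) in FAIRE-seq. With lists of equal length, gained peaks numbered 5319 (drought) and 6062 (salt) in DNase-seq and 15298 (drought), 11762 (heat) and 15846 (salt) in FAIRE-seq. Lost peaks numbered 10665 (cold), 8260 (drought), 15906 (heat) and 5815 (salt) in DNase-seq and 11855 (drought) and 9636 (heat) in FAIRE-seq. Genes gained in both assays numbered 1066 (cold), 558 (drought) and 351 (salt). Genes lost in both assays numbered 1305 (cold), 689 (drought) and 1104 (salt). List members gained numbered 9 (drought) and 4 (salt) in DNase-seq. The percentiles of the list of a stress were 99.8 (drought), 95.5 (heat) and 99.2 (salt) in DNase-seq. Flank shares of gained peaks were 19.2% (cold), 19.0% (drought) and 25.6% (heat) in DNase-seq and 5.13% (drought), 8.01% (heat) and 4.86% (salt) in FAIRE-seq. Flank shares of lost peaks were 7.61% (cold), 4.88% (drought) and 13.7% (salt) in DNase-seq and 19.8% (cold), 28.1% (drought), 17.1% (heat) and 28.2% (salt) in FAIRE-seq. With the narrow gene-end window, genes gained in both assays numbered 142 (cold), 78 (drought), 886 (heat) and 12 (salt). Genes lost in both assays numbered 570 (cold), 387 (drought), 244 (heat) and 503 (salt). List members gained numbered 3 (cold), 2 (drought) and 2 (salt) in FAIRE-seq. The percentiles of the list of a stress were 99.8 (heat) in FAIRE-seq. With summits matched within 150 bp, gained peaks numbered 15152 (cold), 5904 (drought), 20838 (heat) and 5102 (salt) in DNase-seq and 15577 (cold) in FAIRE-seq. Lost peaks numbered 17181 (drought), 12919 (heat) and 19119 (salt) in FAIRE-seq. Flank shares of gained peaks were 13.1% (cold), 8.71% (drought) and 21.0% (heat) in DNase-seq. Flank shares of lost peaks were 7.61% (cold) and 10.4% (salt) in DNase-seq and 14.8% (cold), 19.4% (drought), 13.5% (heat) and 19.3% (salt) in FAIRE-seq. With the whole gene and 1000 bp either side, genes gained in both assays numbered 2869 (cold), 658 (drought), 7544 (heat) and 686 (salt). Genes lost in both assays numbered 7153 (cold), 4485 (drought), 3315 (heat) and 4371 (salt). List members gained numbered 13 (cold), 23 (drought) and 11 (salt) in FAIRE-seq and 4 (drought) in DNase-seq. The percentiles of the list of a stress were 98.3 (drought) and 94.0 (heat) in DNase-seq. With the wide gene-end window, genes gained in both assays numbered 2908 (cold), 842 (drought), 8553 (heat) and 658 (salt). Genes lost in both assays numbered 7450 (cold), 5204 (drought), 3469 (heat) and 5148 (salt). List members gained numbered 13 (cold), 26 (drought) and 13 (salt) in FAIRE-seq and 6 (drought) in DNase-seq. The percentiles of the list of a stress were 99.8 (drought) and 95.5 (heat) in DNase-seq. With equal numbers of strongest summits, shares of strongest summits within genes were 95.3% (control) in DNase-seq and 65.5% (drought), 51.0% (heat) and 65.0% (salt) in FAIRE-seq. Flank shares of strongest summits were 2.21% (control) in DNase-seq and 19.4% (drought), 32.1% (heat) and 20.4% (salt) in FAIRE-seq.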

Other observations

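Among genes that do not code for protein, pseudogenes and small nucleolar RNA genes differed between the lists as well. Other kinds did not all change alike. From control to heat, the DNase-seq share went from 70.4% to 68.1% for long noncoding RNA genes and from 59.5% to 58.0% for microRNA genes. It went from 80.5% to 72.5% for transfer RNA genes and from 71.2% to 51.4% for transcribed pseudogenes. In DNase-seq, 74.0% (95% Wilson interval 72.6 to 75.3) of 3917 pseudogenes had a summit at an end in control, against 43.4% (41.9 to 45.0) under heat, 60.8% under cold, 58.8% under drought and 70.9% under salt. In FAIRE-seq the shares were 65.0% in control, 70.2% under heat, 61.2% under cold, 74.7% under drought and 75.3% under salt. Of 287 small nucleolar RNA genes, 69.0% (63.4 to 74.1) had a DNase-seq summit in control, 90.9% (87.1 to 93.7) under heat, 81.9% under cold, 60.3% under drought and 50.5% (44.8 to 56.3) under salt. In FAIRE-seq the share was 92.7% (89.1 to 95.2) in control, 93.0% under heat, 87.1% under cold, 85.0% under drought and 84.7% (80.0 to 88.4) under salt. For protein-coding genes the DNase-seq share was 72.7% in control, 74.5% under heat, 72.3% under cold, 60.6% under drought and 60.5% under salt, and the FAIRE-seq share 80.7%, 83.5%, 71.6%, 82.8% and 81.1% in the same order.

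Gene-poor regions held different shares of gained and lost peaks in most comparisons. The 23 of 116 bins of 1 Mb with the fewest protein-coding genes held 18.6% (18.3 to 18.9) of control DNase-seq peaks, 27.5% (27.0 to 28.0) of those lost under heat and 5.53% (5.16 to 5.92) of those gained. Under cold they held 25.4% of the lost and 9.68% of the gained peaks. Of the DNase-seq peaks gained under salt they held 55.5% (53.2 to 57.9), against 11.04% of those lost, and of those gained under drought 33.5% (30.6 to 36.5), against 18.2% of those lost. In FAIRE-seq they held 15.5% (15.3 to 15.8) of control peaks. They held 17.3% of the FAIRE-seq peaks gained under salt and 12.2% of those lost, 16.1% and 11.3% under drought, 18.2% and 14.5% under cold, and 15.5% of each under heat.

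Gene families were searched by shared symbol, without a plan. Over 59 families and 944 comparisons, 36 lay over percentile 97.5 and 41 under 2.5, where 23.6 would lie on each side by chance if they were independent. Among the most extreme, 11 of 81 LCR genes, which encode small cysteine-rich proteins, gained a DNase-seq peak under heat (random 26.9) and 5 of 121 MYB genes under cold (random 19.4). Lost DNase-seq peaks were found at 16 of 28 CHX genes, cation/proton exchangers, under heat (random 7.41), and at 16 of 24 SYP genes, syntaxins, under drought (random 8.09). These families were picked out after their values were seen.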
